A study of Mus musculus with 6 samples.

How the data were processed

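RNA sequencing measured transcript levels in inguinal white adipose tissue, the subcutaneous fat depot of the groin, from 6 female C57BL/6N mice. Per the labels, 3 mice went through 8 weeks of sleep fragmentation and then 2 weeks of sleep recovery, and 3 mice were controls. Each library came from 1 mouse, and the mice were fasted for 10 h before tissue collection. The fat depot can also hold lymph node, mammary gland, muscle and skin, so marker lists for these tissues were among the gene lists used.

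Per the submitters' processing notes, the named tools were CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3, with the mouse genome build mm8. The deposited table holds a signal value for each of 25894 Ensembl gene identifiers in each library. These values behave as read counts divided by 1 size factor per library. Dividing each column by its smallest value above 0 gave whole reads for 100% of values in every library, within 0.02 of a whole number. DESeq2 size factors of the recovered reads were equal to the recovered divisors, from 0.8847 to 1.3183. The recovered reads summed to between 15610201 and 19703569 per library. The build of the reference annotation used here differs from mm8, so no coordinates are given. Gene symbols came from a table of identifiers and symbols, which left 33 identifiers unmatched. The counting could split reads between near-identical genes and pseudogenes, so values of ribosomal protein genes and their pseudogenes are uncertain.

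The test was written before the data were examined for a table of raw counts, with a fallback for normalised values. The table holds a size-factor-scaled signal, a unit that neither plan named, and the fallback was used. limma with an intensity trend (limma 3.58.1, R 4.3.3) was run on log2(value + 1) for the 22290 genes with a mean of at least 1, with Benjamini-Hochberg adjustment and an FDR threshold of 0.05. Fold changes are on this log2(value + 1) scale, which understates changes of low genes. The count tests edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. On recovered reads, edgeR called 0 of 16141 genes and DESeq2 called 0, with 118 adjusted p-values given as NA by DESeq2.

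Also fixed then were 45 gene lists for adipose metabolism, hormones, the clock, inflammation, stress responses and cell types. Each was tested against all other genes with limma's camera on log2(value + 1), two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 45 lists. The plan had named log2 CPM with TMM and a prior count of 2 as the input. The estimated correlation within each list and the fry test stood beside camera. Genes named were fixed by rule: those past the threshold by size, up to a limit per list, 12 genes fixed in advance, the 10 smallest unadjusted p-values with a mean CPM of at least 1 if fewer than 10 genes passed, and the 2 most abundant members of a list as examples. Genes named outside the rule are said to be chosen after their values were seen. Values of some list members are not reported here.

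On simulated counts drawn for this comparison from the spread of the 6 libraries, limma on 21244 genes recovered 0% of genes changed 2-fold, 58.2% of those changed 4-fold and 90.9% of those changed 8-fold, with 11 false among 110 calls. The changed genes were drawn only from genes with a mean of at least 50, so these recovery rates do not cover lower genes. DESeq2 gave 61 false among 179 calls on the same simulated data. A simulated shifted list had a camera adjusted p of 2.27e-17 with the preset correlation and 0.0257 with an estimated correlation, and 0 of 40 unshifted lists were called. The simulated genes were drawn independently, whereas the estimated correlation within the real cell cycle list was 0.887. The 0 of 40 therefore cannot show how often lists of correlated genes are called falsely. The alternatives covered normalisation, test, filters, pseudocount, thresholds, replicate block, each mouse left out, libraries high in markers of other tissues, and trends of each library on GC content and transcript length. GC content and length came from GENCODE M21 transcripts and were known for 99.87% of the genes tested. The trends were removed with splines of 4 degrees of freedom.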

Results

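The table covers 6 libraries of inguinal fat, 3 from mice with sleep fragmentation followed by recovery (called fragmented, recovered 1 to 3) and 3 from control mice (control 1 to 3). Recovered reads ranged from 15610201 to 19703569 per library. The comparison asks which transcripts in fat still differ from controls after 2 weeks of recovery sleep.

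The immediate early genes, transcription factors and regulators that are induced within minutes of a stimulus, were higher as a group in the fragmented, recovered mice, with a median log2 change of 0.99 over 20 measured members (camera adjusted p = 8.75e-08, and adjusted p = 0.532 with an estimated correlation). Cell cycle genes were lower as a group, with a median of -1.22 over 23 members. Genes of B and plasma cells, neutrophils, and T and NK cells were also lower as groups, and oxidative phosphorylation, ribosomal protein and mammary epithelium genes were higher. For these lists the adjusted p was between 0.843 and 0.871 with an estimated correlation. No single gene passed the threshold.

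Of 22290 genes tested by limma, 0 passed an FDR of 0.05, and the smallest adjusted p was 0.697. At an unadjusted p under 0.05 there were 723 higher and 478 lower genes, against 1114 expected by chance. edgeR gave 0 calls with 762 at an unadjusted p under 0.05, and DESeq2 gave 0 calls with 1186. All 3 fragmented, recovered mice lay above all controls for 1118 genes and below for 797, together 8.59% of genes against 10% by chance. Leaving out control 1 gave 844 calls, 563 higher and 281 lower, and limma-voom with quality weights gave 1023, 699 higher and 324 lower. The smallest limma-voom adjusted p with quality weights was 0.0451, so all 1023 lay close to the threshold. The median log2 change over all genes was 0.02, and 0.13 when reads were scaled by library size alone.

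The genes with the smallest p-values did not pass the threshold, each with a limma adjusted p of 0.697. Without control 1, all but Rps27a and Rps13-ps2 of the 10 passed, with limma adjusted p-values from 0.0181 for Gprin3 to 0.0385 for Gm8430. With GC content and length trends also removed, only Syn2 (limma adjusted p = 0.0347) and Sncg (0.0494) of the 10 passed. Nnat, an imprinted gene of adipocytes and neurons, had normalised values of 6284 ± 4475 (SD, n = 3) in fragmented, recovered mice and 1239 ± 634.5 in controls, a log2 difference of 2.24 with an SE of 0.48. Sncg, a synuclein made by adipocytes, had a difference of 2.34 (SE 0.62), Syn2, a synaptic vesicle protein, 1.37 (SE 0.30), and Pcolce, an enhancer of procollagen processing, 1.44 (SE 0.38). Zfp36, which destabilises inflammatory messenger RNAs, had values of 1049 ± 165 against 492 ± 107, a difference of 1.10 (SE 0.26). Rps27a had a difference of 1.13. The genes at lower levels in the fragmented, recovered mice were Gm8430 at -1.41, Gm17066 at -1.66, Gprin3 at -1.77 and Rps13-ps2 at -1.23.

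Genes fixed in advance for adipose function did not pass either. Adipoq, the adiponectin gene, had a log2 difference of 0.41 (SE 0.40), and Lep, which encodes leptin, of -0.01 (SE 0.57). Ucp1, the thermogenic uncoupling protein, had 0.66 (SE 0.93), Fasn, fatty acid synthase, -0.78 (SE 0.63), and Slc2a4, the insulin-responsive glucose transporter, 0.29 (SE 0.24). Lipe, hormone-sensitive lipase, had 0.91 (SE 0.42), with an adjusted p by limma of 0.697 with all 6 mice and 0.0393 without control 1. Lipe did not pass without control 1 once GC content and length trends were also removed. The clock genes Nr1d1, Dbp and Per2 had 0.30, 0.91 and 0.33. The inflammatory genes Tnf and Ccl2 had -0.17 and 0.32, and Adgre1, a macrophage marker, had -0.46. For Tnf the direction turned to 0.52 with edgeR on recovered reads.

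Of the 45 lists, 15 passed the threshold with the preset correlation, 10 higher and 5 lower, 0 passed with an estimated correlation, and 0 passed by fry in either form. With GC content and length trends of each library removed, 17 lists passed, 7 higher and 10 lower, and 11 of the 15 were among them. In the immediate early list, 17 members were higher and 3 lower, 10 had an unadjusted p under 0.05, 8 passed when adjusted over the list alone and 0 over all genes. Its most abundant members were Klf2, at 0.95 (SE 0.26), and Klf4, at 1.07 (SE 0.32). Fos and Jun, chosen after their values were seen, had differences of 1.99 (SE 0.59) and 1.04 (SE 0.29), with all 3 fragmented, recovered mice above all controls. For Fos the margin was narrow, with normalised values of 421.6 in fragmented, recovered 3 and 415.7 in control 1. The list median was above 0 in each fragmented, recovered mouse (0.53, 0.22 and 0.53) and below 0 in each control (-0.14, -0.36 and -0.70). With each mouse left out in turn the list passed, with medians from 0.77 to 1.15. It also passed with GC content and length trends removed, at 0.55.

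**Figure D1:**
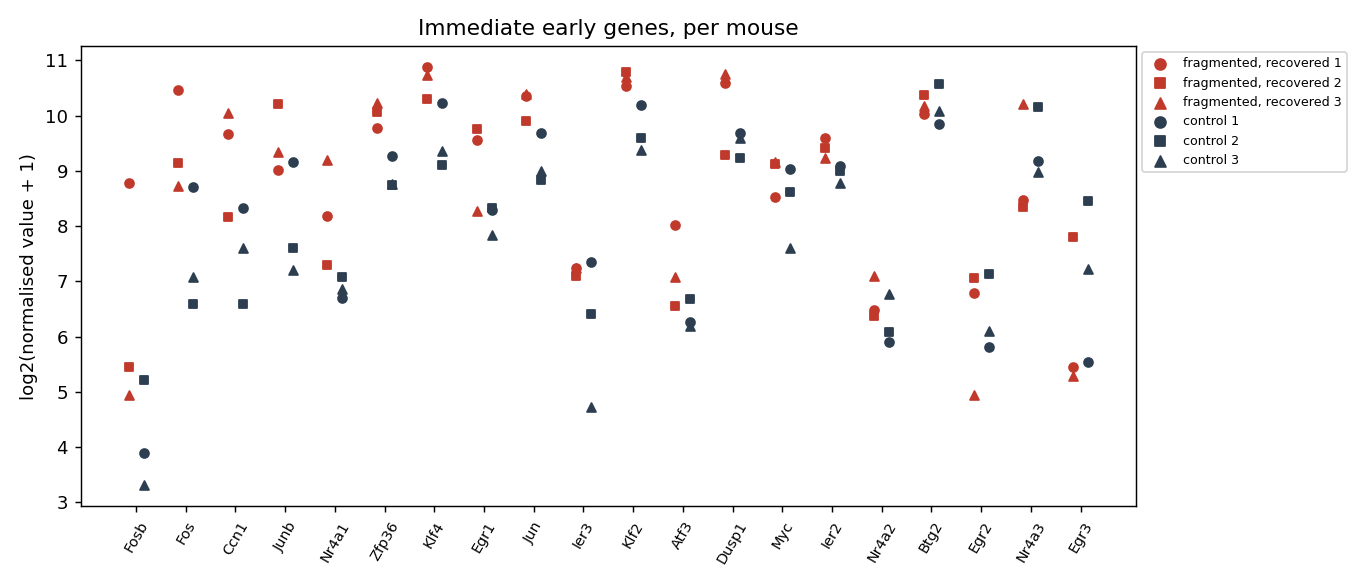
Each point is 1 mouse, with the normalised value plus 1 on a log2 scale on the y axis and the 20 immediate early genes along the x axis, ordered by log2 difference; red is fragmented, recovered and dark blue is control. For Fos and Jun the 3 red points lie above the 3 control points, for Fos by a narrow margin.

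Cell cycle genes were lower in all 23 members, 7 of them with an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 1.14e-09, and adjusted p = 0.843 with an estimated correlation). Mki67 and Top2a, both made by dividing cells, had log2 differences of -1.75 (SE 0.81) and -2.20 (SE 0.85) and did not pass. The cell cycle list passed with each mouse left out in turn, at -1.95 without fragmented, recovered 2, -1.86 without control 1, -0.79 without fragmented, recovered 1 and -0.79 without control 2. It had -0.34 and did not pass without fragmented, recovered 1 and control 2 together, the libraries highest in muscle markers. That fit left each group with a library high and a library low in B and plasma cell genes. Their medians were 3.14 and -3.27 in fragmented, recovered 2 and 3, and 2.65 and -3.60 in control 3 and control 1. B and plasma cell genes had a median of -1.86 (adjusted p = 0.0028, and adjusted p = 0.867 with an estimated correlation), with 18 of 19 members lower. Igkc had -0.92 (SE 1.23) and Ighm -1.09 (SE 1.31). T and NK cell genes had a median of -0.71 (adjusted p = 0.0378, and adjusted p = 0.871 with an estimated correlation). Lck had -0.73 (SE 0.99), turning to 0.11 with edgeR on recovered reads, and Cd4 had -0.71 (SE 1.02). Neutrophil genes had a median of -2.00 (adjusted p = 8.86e-04, and adjusted p = 0.843 with an estimated correlation), with S100a8 at -3.36 (SE 1.51) and Ltf at 0.04 (SE 0.69).

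These lymphoid and neutrophil lists were high in libraries of both groups. The B and plasma cell median was 3.14 in fragmented, recovered 2, 4.16 in control 2 and 2.65 in control 3, and -2.79, -3.27 and -3.60 in the other libraries. Lymph node stroma genes followed with 2.38, 1.42 and 0.97 in the same 3 libraries, and that list did not pass (camera adjusted p = 0.411). Cell cycle medians were also highest in these 3 libraries, at 0.53, 1.61 and 0.91. They were -1.48, -1.14 and -0.58 in fragmented, recovered 1 and 3 and control 1. Leaving out these 3 libraries would leave 2 fragmented, recovered mice against control 1 alone. Without the 2 libraries highest in muscle markers, the B and plasma cell, T and NK cell and neutrophil medians were 0.32, 0.58 and -0.58, none passing. With the B cell marker score as a covariate, the T and NK median turned to 0.25 and did not pass, and the neutrophil list passed at -0.62. Of the 15 lists, 11 passed in the same direction with that covariate, and 3 kept their direction and did not pass. The cell cycle median fell from -1.22 to -0.58 with that covariate. The B and plasma cell list had -0.41 without control 2, -1.37 without control 3, -0.99 without fragmented, recovered 1 and -0.60 without fragmented, recovered 3, and passed in none of these. The T and NK list had -0.003, -0.067 and -0.12 without control 2, fragmented, recovered 1 and fragmented, recovered 3, and the neutrophil list -0.92 without control 2, all short of the threshold. The B and plasma cell, T and NK cell and neutrophil lists passed at -4.35, -1.82 and -3.54 without fragmented, recovered 2 and at -4.63, -1.35 and -3.92 without control 1.

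Cholesterol synthesis genes had a median of -0.32, with 18 of 23 members lower (adjusted p = 0.00935, and adjusted p = 0.843 with an estimated correlation). Insig1, which holds back sterol synthesis, had -0.71 (SE 0.28) and Hmgcs1, an early enzyme of the pathway, -0.40 (SE 0.27), and neither passed. Without control 1 the list had -0.25 and did not pass, and without fragmented, recovered 1 it passed at -0.19.

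Oxidative phosphorylation genes of the nucleus were higher as a group with a median of 0.43, 47 of 59 members higher (adjusted p = 8.06e-04, and adjusted p = 0.867 with an estimated correlation). Atp5b had 0.18 (SE 0.36) and Atp5a1 -0.38 (SE 0.27). Cytosolic ribosomal protein genes had a median of 0.36, 68 of 83 higher (adjusted p = 6.98e-05, and adjusted p = 0.867 with an estimated correlation), with Rpl4 at 0.03 and Rps3a1 at 0.11. Against control 1 alone, the control low in lymphocyte markers, fragmented, recovered 1 and 3 had medians of -0.52 and -0.35 for these lists, a comparison with 1 mouse. With GC content and length trends removed they had 0.14 (adjusted p = 0.423) and 0.18 (adjusted p = 0.311) and did not pass. With the B cell marker score as a covariate, the oxidative phosphorylation list had 0.18 (adjusted p = 0.193) and did not pass, and the ribosomal list passed at 0.23. Without the 2 libraries highest in muscle markers they had 0.019 and 0.15, neither passing. In control 1 the oxidative phosphorylation median was 0.74, above every fragmented, recovered mouse, while controls 2 and 3 had -0.71 and -0.60. The oxidative phosphorylation list had 0.14, 0.20 and 0.32 without control 2, control 3 and fragmented, recovered 1, and the ribosomal list 0.13 and 0.14 without control 3 and fragmented, recovered 1, none passing. Without control 1 these lists passed at 0.91 and 0.64, and the ribosomal list passed at 0.55 without fragmented, recovered 3.

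Mammary epithelium genes were higher as a group, with a median of 0.86 and 25 of 28 members higher (adjusted p = 2.64e-05, and adjusted p = 0.843 with an estimated correlation). Krt19, an epithelial keratin, had 1.56 (SE 0.65), and Prlr, the prolactin receptor, -0.16 (SE 0.34). Skin keratinocyte and hair follicle genes had a median of 0.85 (adjusted p = 0.0187, and adjusted p = 0.843 with an estimated correlation), with Ly6d at 1.41 and Trp63 at 0.23. The mammary list passed with each mouse left out in turn, at 1.58 without control 1, 0.50 without control 2 and 0.53 without control 3. Control 1 had a mammary median of 0.77 and controls 2 and 3 had -1.03 and -0.99. For fragmented, recovered 1 and 3 against control 1 alone, the mammary and skin lists both turned to lower, a comparison with 1 mouse. With GC content and length trends removed the mammary list passed at 0.56 and the skin list had 0.57 and did not pass. Without the 2 libraries highest in muscle markers the mammary list passed at 0.68 and the skin list had 1.04 and did not pass. Skeletal muscle genes had a median of 1.41 (adjusted p = 0.00462, and adjusted p = 0.867 with an estimated correlation), with Acta1 at 1.39 (SE 1.57) and Myh4 at 2.21 (SE 3.48). The muscle median was 4.47 in fragmented, recovered 1, and the list turned to -0.39 without that mouse. It did not pass without the 2 libraries highest in muscle markers, at 0.84. It passed at 2.82 without fragmented, recovered 3 and at 2.36 without control 2. It had 1.51 without control 1 and 0.30 without control 3, and the skin list had 0.70, 0.50 and 0.45 without control 2, control 3 and fragmented, recovered 2, none passing.

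Smooth muscle and pericyte genes had a median of 0.41, with 12 of 13 members higher (adjusted p = 0.00462, and adjusted p = 0.843 with an estimated correlation), Rgs5 at 0.08 and Mcam at 0.38. Type I interferon response genes had a median of 0.51 (adjusted p = 0.00935, and adjusted p = 0.843 with an estimated correlation), with Ifi27l2a at 0.91 and Gbp2 at 0.07. Heat shock protein genes had a median of 0.48 (adjusted p = 0.0187, and adjusted p = 0.843 with an estimated correlation), with Hspa8 at 0.25 and Hsp90aa1 at -0.44. Adipokine genes had a median of 0.46 (adjusted p = 0.0378, and adjusted p = 0.867 with an estimated correlation), with Cfd, which encodes adipsin, at 0.86 (SE 0.55). The adipokine list had 0.13 (adjusted p = 0.311) with GC content and length trends removed and 0.29 (adjusted p = 0.250) with the B cell marker score as a covariate, neither passing. Without the 2 libraries highest in muscle markers the interferon, heat shock, smooth muscle and adipokine lists had 0.33, 0.45, 0.43 and 0.069, none passing. Without fragmented, recovered 1 the interferon, heat shock and adipokine lists had medians of 0.27, 0.36 and 0.24 and did not pass. Without control 2 the smooth muscle, heat shock and adipokine lists had 0.34, 0.55 and 0.28, without control 3 the interferon and heat shock lists had 0.24 and 0.30, and without fragmented, recovered 3 the adipokine list had 0.31, none passing. Without fragmented, recovered 2 the smooth muscle list passed at 0.64.

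**Figure D2:**
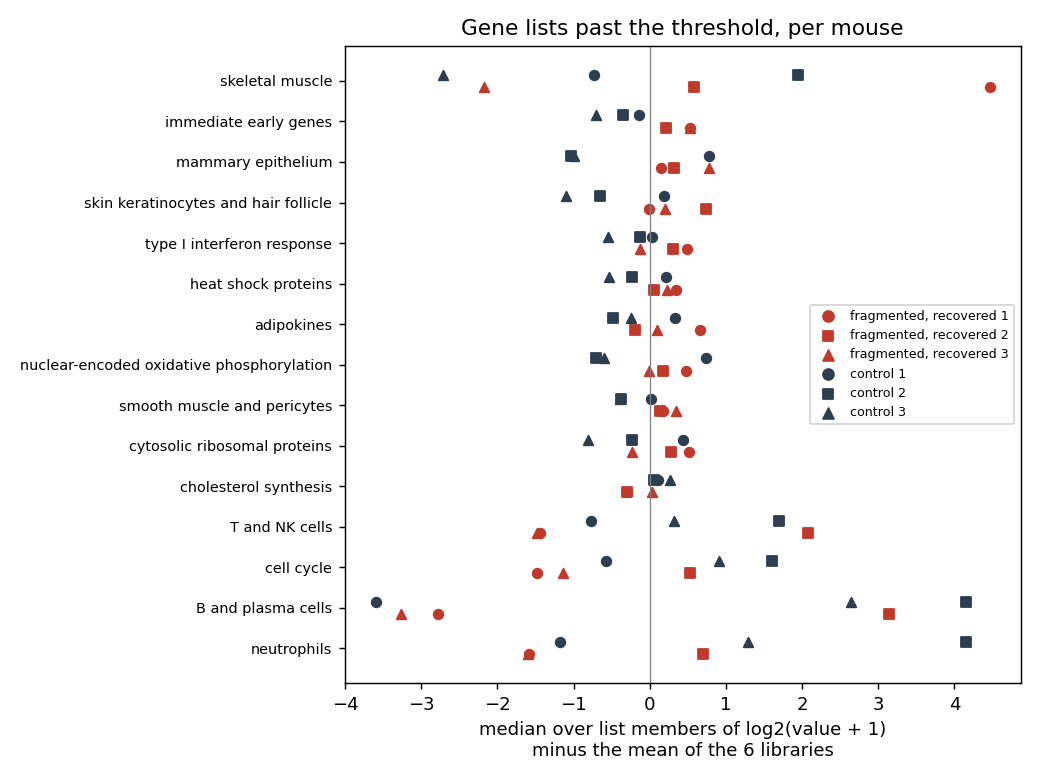
Each point is 1 mouse, with the median over the members of a list, as log2(value + 1) minus the mean of the 6 libraries, on the x axis and the 15 lists past the threshold on the y axis; red is fragmented, recovered and dark blue is control. The B and plasma cell medians run from -3.60 to 4.16, with mice of both groups at either side. The immediate early, smooth muscle and cholesterol synthesis medians separate the groups.

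The other 30 lists did not pass in the main fit. Some of them, not named here, passed with trends removed, with the replicate block or without the 2 libraries highest in muscle markers. With the replicate block, for example, 20 lists passed, the 15 of the main fit among them. Medians were -0.10 for lipogenesis, 0.04 for lipolysis, -0.23 for fatty acid uptake, 0.03 for fatty acid oxidation, 0.01 for thermogenesis, 0.16 for glycolysis, 0.06 for adipocyte identity and 0.13 for the circadian clock. Insulin signalling had -0.31 (adjusted p = 0.0583) and glucocorticoid-responsive genes 0.43 (adjusted p = 0.0552). Inflammatory cytokine genes had a median of 0.06, with the camera direction lower, and macrophage genes -0.17. Receptors for microbial products had -0.36, MHC class II -0.35 (adjusted p = 0.0583), mast cells -0.45 and NADPH oxidase -0.47. Blood endothelium had 0.26, lymphatic endothelium -0.38, progenitors and fibroblasts 0.25, extracellular matrix 0.11, Schwann cells and nerve 0.21 and red blood cells -0.05. Hypoxia had -0.04, endoplasmic reticulum stress 0.15, antioxidant defence 0.22, senescence and p53 targets 0.23, mitochondrially encoded transcripts -0.00, nuclear-retained RNAs 0.45 and histones 0.04.

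The first principal component held 42.3% of the variance and the second 23.5%. Controls 2 and 3 lay at 116.2 and 111.5 on the first, control 1 at -77.0, and the fragmented, recovered mice at -90.6, 8.8 and -69.0. The Spearman rho across genes of a library's deviation on GC content was -0.41 and -0.42 in controls 2 and 3 and between 0.19 and 0.55 in the other libraries. Genes are not independent replicates. Control 1 had its highest rank correlation across genes, 0.974, with fragmented, recovered 3.

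**Figure D3:**
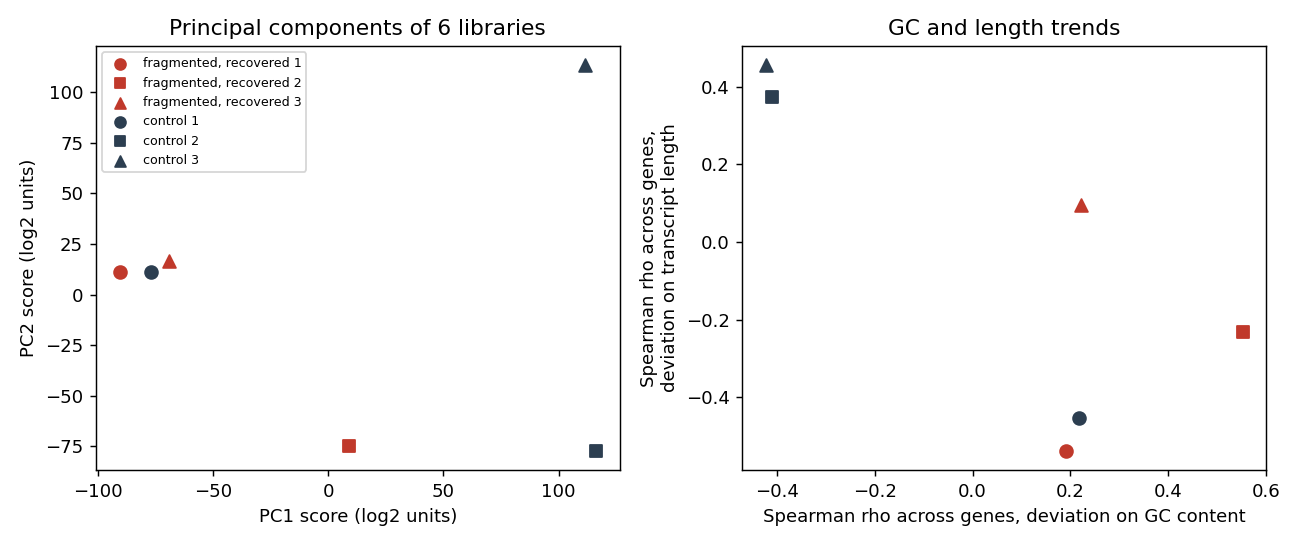
The left panel plots the second against the first principal component score of each library, and the right panel the Spearman rho across genes of each library's deviation on transcript length against that on GC content; red is fragmented, recovered and dark blue is control. Controls 2 and 3 lie apart from the other 4 libraries on the first component and on GC content.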

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

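Settings that removed GC and length trends, left out libraries high in lymphocyte or muscle markers, or used the B cell score were chosen after seeing the data. So were those that recomputed the filter, used a mean of at least 10 or, for lists, used a pseudocount of 0.1. The plan for raw counts named edgeR with TMM and, for lists, log2 CPM with TMM and a prior count of 2. Both were run on recovered reads, and that list input gave 13 lists, 9 higher and 4 lower. With all 6 mice, the count of 0 genes held under every normalisation, filter and test run, and with the replicate block, except these: limma-voom with quality weights gave 1023, and an unadjusted p under 0.05 with a log2 change of at least 1 gave 736. The 1023 all had a limma-voom adjusted p of 0.0451 or above, close to the threshold. Leaving out each mouse gave 0 to 844 genes, the 844 without control 1, on the genes tested with all 6 mice. With the filter recomputed on the 5 libraries left it gave 1078. With trends removed and control 1 left out it was 59, and 62 with the filter recomputed. The genes called without control 1 and by quality weights shared 710. Lists past the threshold were 0 with an estimated correlation, 0 by fry, 7 without the 2 libraries highest in muscle markers, and 9 to 22 with each mouse left out, 9 without control 2. The T and NK list did not pass on log2 CPM with TMM (adjusted p = 0.0651 to 0.0752) or with a mean of at least 10 (0.0779), nor did skin with TMM (0.0745 to 0.0779) or library size only (0.116), skeletal muscle with library size only (0.0591) or adipokines with a pseudocount of 0.1 (0.0535). The first component held 60.6% on the 500 most variable genes, 53.3% on log2 CPM with TMM and 52.3% with library size only. Besides the trends and lymph node content, only splits of the libraries and counts of mouse pairs were examined, and no other cause was tested.

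Whether the replicate numbers pair the mice cannot be told from these values. Deviations of same-numbered mice all correlated positively, at 0.177, 0.393 and 0.042, while fragmented, recovered 3 correlated better with control 1, at 0.208. The replicate block gave 0 genes, with a smallest limma adjusted p of 0.0705 against 0.697 without it, and 20 lists.

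Directions turned for genes and lists as follows, none of the genes being past the threshold. With trends removed, log2 differences were 0.016 for Lep, -0.055 for Nr1d1, -0.079 for Atp5b, -0.073 for Ltf, 0.48 for Prlr, -0.16 for Rpl4 and -0.15 for Rps3a1. For Tnf and Lck they were 0.48 and 0.071 with DESeq2, 0.52 and 0.11 with edgeR, 0.48 and 0.072 with DESeq2 size factors, 0.70 and 0.32 with library size only, and 0.56 and 0.16 with upper-quartile factors. Prlr had 0.075 with library size only, and Lep 0.004 with limma-voom. With the B cell score as a covariate, T and NK cells had 0.25.

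Without the 2 libraries highest in muscle markers, oxidative phosphorylation had 0.019, with the camera direction lower, adipokines 0.069, with the camera direction lower, T and NK cells 0.58, B and plasma cells 0.32, Adipoq -0.040, Tnf 1.32, Ccl2 -0.10, Atp5b -0.21, Gbp2 -0.021, Lck 0.57, Cd4 0.62, Igkc 0.81, Ighm 0.48, Prlr 0.042, Mcam -0.13, Hspa8 -0.028, Rpl4 -0.046 and Rps3a1 -0.026. Leaving out the 3 libraries high in lymphocyte markers left fragmented, recovered 1 and 3 against control 1 alone, which is assumed to vary like the other group, so these values show how that mouse differs and no call is drawn from them. There, oxidative phosphorylation had -0.52, B and plasma cells 0.14, mammary epithelium -0.31, skin -0.20, ribosomal proteins -0.35, Lep 1.69, Ucp1 -1.84, Lipe -0.005, Nr1d1 -0.22, Atp5b -0.33, Gbp2 -0.32, Cd4 0.23, Igkc 0.17, Ighm 0.96, Ltf -1.53, Krt19 -0.39, Trp63 -0.42, Hsp90aa1 0.076, Rpl4 -0.17 and Rps3a1 -0.27.

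With each mouse left out in turn, values ran from -0.52 to 2.74 for Acta1, -0.078 to 0.47 for Atp5b, -0.31 to 0.88 for Ccl2, -1.78 to 0.14 for Cd4, -0.11 to 0.25 for Gbp2, -2.64 to 0.20 for Ighm, -2.09 to 0.42 for Igkc, -0.76 to 0.55 for Lep, -0.42 to 0.85 for Ltf, -1.25 to 5.96 for Myh4, -0.49 to 0.14 for Prlr, -0.003 to 0.20 for Rgs5, -0.12 to 0.17 for Rpl4, -0.11 to 0.31 for Rps3a1, -1.13 to 0.86 for Tnf, -0.28 to 0.66 for Trp63 and -0.063 to 1.66 for Ucp1. Of 55 named genes, 21 kept their sign and moved by over 1.5 times, from -1.35 to -0.40 for Fasn, 0.093 to 0.71 for Adipoq, 0.29 to 1.38 for Dbp, -0.69 to -0.16 for Adgre1, -5.12 to -1.65 for S100a8, 0.14 to 0.41 for Slc2a4, 0.56 to 1.40 for Lipe, 0.12 to 0.64 for Nr1d1, 0.16 to 0.60 for Per2, 0.42 to 1.31 for Cfd, 0.37 to 1.58 for Ifi27l2a, -1.99 to -0.012 for Lck, 1.00 to 2.48 for Krt19, 0.89 to 2.13 for Ly6d, 0.059 to 0.64 for Mcam, 0.002 to 0.42 for Hspa8, -0.65 to -0.28 for Hsp90aa1, -0.59 to -0.24 for Hmgcs1, -2.60 to -1.02 for Mki67, -3.07 to -1.45 for Top2a and -0.95 to -0.44 for Igf1. Oxidative phosphorylation ran from 0.14 to 0.91, with the camera direction lower without control 2, and skeletal muscle from -0.39 to 2.82. Without control 1, 15 named genes passed the threshold: Gm8430, Nnat, Syn2, Gm17066, Gprin3, Zfp36, Pcolce, Sncg, Lipe, Krt19, Ly6d, Klf2, Klf4, Fos and Jun. Of these 15, only Syn2 and Sncg passed when GC and length trends were also removed. At the depth of these libraries the spread between mice limits the calls, with a median SE of 0.327 on the log2 scale for genes of mean 50 or more.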

Other observations

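Insulin signalling genes did not pass the threshold as a list (camera adjusted p = 0.0583), with 19 of 31 members lower. Pik3r1 and Igf1, chosen after their values were seen, had log2 differences of -0.66 (SE 0.27) and -0.74 (SE 0.33), neither past the threshold. Pik3r1 encodes a regulatory subunit of the phosphoinositide kinase downstream of the insulin receptor, and Igf1 encodes a growth factor.

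Tests chosen after the result was seen were the counts of mouse pairs, the stroma difference within a group, the splits for genes, the B cell marker score as a covariate, whose possible outcomes were written before its values were seen, and every setting that removed GC and length trends, left out libraries high in tissue markers or recomputed the filter. The standard errors set beside the bounds below were also added after the values were seen. Each is the SE of the group term in a fit of the list's mean score over libraries, not of the median. On the bound alone, the cell cycle value would have met the prediction of a lymph node cause. The immediate early value after trend removal would have missed the prediction of a trend cause. The folds set beside the counts without control 1, and the interval for the lymphoid markers among them, were added after the values were seen too. The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest of the others 702. Against a count of 0 all 10 splits must give as many, so this share decides nothing. For lists the real split gave 15 and the highest other 23, with 6 of 10 giving as many. The split with 702 genes sets fragmented, recovered 1 and 3 and control 1 against the rest, which follows lymphocyte markers and points to a structure of the samples.

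Immediate early genes were higher in the fragmented, recovered mouse in 9 of 9 pairs of mice. Such a full separation, in either direction, has a chance of 10% for each list. The medians of the smooth muscle, cholesterol synthesis and microbial product receptor lists separated the groups too. With the B cell marker score as a covariate the immediate early median was 0.78 against 0.99 without it. It lay above the bound of 0.50 by more than the SE of the mean score, 0.17. As far as that SE holds for a median, this is weak evidence against lymph node content as the whole cause. The SE comes from a fit of 6 libraries with a covariate, so that cause is not excluded. With GC and length trends removed this median was 0.55 (SE of the mean score 0.15), within that SE of the bound of 0.50. These trends may therefore account for part of it, and the share cannot be told apart from the group. A lasting difference from sleep fragmentation and a difference in handling at tissue collection both stay open, and neither was tested.

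Lymphocyte and cell cycle lists passed as lower with the preset correlation and did not pass with an estimated correlation (adjusted p from 0.843 to 0.871). The B and plasma cell list did not pass in 4 of the 6 fits with a mouse left out. Lymph node stroma genes were 3.51 log2 units higher in fragmented, recovered 2 than in the mean of the other mice of its group, consistent with unequal amounts of lymph node in the dissected fat. The cell cycle median was -0.58 (SE of the mean score 0.21) with the B cell score as a covariate and -1.22 without it. The value with the covariate was within that SE of the bound of -0.61. Cell cycle genes were lower in 8 of 9 pairs of mice, a count made without the covariate that says nothing about what remained after it. Fragmented, recovered 1 and 3 and control 1 against the rest gave an absolute cell cycle median of 2.12, against 1.22 for the real split. Without fragmented, recovered 1 and control 2, each group kept a library high and a library low in B and plasma cell genes. The cell cycle list did not pass in that fit, which goes with unequal amounts of lymph node but rests on fewer mice. What remained after the covariate cannot be told apart from a difference between the groups.

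Without control 1, 844 genes passed, 563 higher and 281 lower, and 59 when GC and length trends were also removed, 58 higher and 1 lower. The median log2 change of the 563 went from 1.72 (median SE 0.29) to 1.22 (0.28) and that of the 281 from -1.26 (0.23) to -0.62 (0.21), and 492 and 177 of them still had an unadjusted p under 0.05, so most of the lost calls ended at the adjusted threshold with smaller folds. On the count alone the trends met what was written for them as the cause, but most of the fold of the higher genes remained, so trends may account for part and the rest cannot be told apart from a group difference that control 1 does not share. Higher genes had a median GC content of 54.7% and length of 1588 nt, lower genes 41.2% and 5648 nt, and all genes 49.1% and 2697.5 nt. Of 48 B cell, T cell and lymph node stroma markers, 0 were among the 844, against 1.82 at the overall share, which decides nothing about lymph node content, and a wrong label on control 1 was not tested. Of 28 mammary epithelium markers 9 were among the 844, and of 59 oxidative phosphorylation genes 20, against 844 of 22290 genes tested. With trends also removed these were 1 and 7. Mammary medians were 0.77 in control 1 and -1.03 and -0.99 in controls 2 and 3. Unequal amounts of mammary gland in the dissected fat were not tested as a cause of these calls.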
